A study of Homo sapiens with 120 samples.

How the data were processed

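The labels describe 120 RNA sequencing libraries of CFPAC-1 cells made with the SMARTer and Nextera XT kits. According to the submitters' processing notes the authors quantified the reads with RSEM against hg19 and deposited 1 table of FPKM values, fragments scaled by transcript length and by the total of the library, with 30504 rows and 120 columns. The values have decimals and their column totals run from 339644 to 817990. For 65 libraries with over 3000 genes the totals varied with a CV of 12.1%, which became 6.5% after each value was multiplied by the transcript length of GENCODE release 29, matched for 69.3% of rows. That release is built on another genome than hg19, so no coordinates were taken from it. The table holds 27118 distinct names, and 1116 names stand on more than 1 row. It has no row for mitochondrially encoded genes, ACTB or GAPDH. It holds no counts, so depth per library is unknown and counts could not be thinned. A relative depth was estimated from the spacing of the lowest values, and on simulated data it was off by up to a factor of 2.0.

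Groups, replicates and doses came from the labels, which also give each library's index pair. Index pairs repeat between the C1 set, the raft rounds and the treatment arms, so each arm, each round and the C1 set was taken as a library pool of its own. Treatment and pool therefore cannot be told apart, while proliferative and nonproliferative rafts of an arm share a pool. The labels name no culture or donor batch. Each p-value in the treatment arms measures the spread between rafts, which may come from 1 culture per arm. For single and paired cells of the isolation experiment the tests planned in the design were not made, because each group then counts as 1 sample. Those comparisons are given as values, with each gene list set against 10000 random lists of genes with like mean expression. The random lists were drawn gene by gene, so members that move together can give an extreme percentile.

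A gene was called detected at an FPKM of 1 or more. Spearman rho with bulk was taken across 10767 genes with a mean bulk FPKM of 1 or more. Differences in genes detected and in rho between proliferative and nonproliferative rafts were tested by permuting labels within arms (100000 resamples, two-sided), and per arm by exact permutation. On simulated data the permutation test gave a p under 0.05 in 5.5% of 200 runs with no shift and in 97.5% with a shift of 3000 genes.

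Expression was compared on log2(FPKM + 1) with limma 3.58.1 (limma-trend, two-sided, Benjamini-Hochberg adjustment, threshold 0.05) in R 4.3.3. A single fit held the 8 groups of the gemcitabine experiment, with the libraries that had at least 1000 genes detected (52 of 64) and the 11560 genes detected in at least 8 of them. Some empty rafts, empty C1 captures and water libraries also reached 1000 genes, so this filter did not separate cells from blanks. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. On simulated data with the same spread, 50 genes were shifted at each size. For proliferation averaged over arms limma recovered 3, 15, 49 and 50 of them at log2 shifts of 1, 2, 4 and 6, for 5 nM against saline 1, 6, 35 and 50, and for saline against untreated 0, 4, 22 and 40, with no call among 11360 unshifted genes. Changes of a log2 of 2 or less were thus mostly beyond reach, and for saline against untreated a shift of 4 was recovered in 22 of 50 genes. Only 1 shuffle was made per comparison, so the lack of calls among unshifted genes says little about false calls. Other splits of the real libraries gave up to 1297 genes for proliferation averaged over arms and 545 for 5 nM against saline.

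Gene lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and with fry, and their members were counted over all genes and adjusted over the list alone. No camera call held after adjustment with an estimated correlation. No member of the blood cell list was measured in the arms, and none of the mitochondrially encoded list in any comparison. The genes named were the 10 higher and the 10 lower with an adjusted p under 0.05 and the largest change among genes detected in at least 0.5 of the libraries of the group where they were higher, with up to 4 passing members per list with the smallest p. MKI67, TOP2A, PCNA, CDKN1A, DCK, CDA, RRM1, RRM2, TYMS and SLC29A1 were named in the main contrasts whatever their p. Where none passed, genes were taken from the 5 with the smallest p. Isolation comparisons used the same rule by size of difference without a p, over genes detected in at least 5 libraries. Pseudogenes, unplaced identifiers, repeated names and names not matched to a coding gene were skipped. Genes named where a list or a setting gave 5 or fewer, CCNB1 in the saline arm, CDKN1A beside it in the untreated arm, the MTRNR2L genes and the values named from empty captures were chosen after their values were seen.

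The groups, tests, gene lists, naming rule and most alternatives were set before the data were examined. The alternatives were quantile normalization, a pseudocount of 0.1, no gene filter or a stricter one, all libraries or those with at least 3000 genes, the number of genes detected as a covariate, only the groups compared, detection at an FPKM of 5, and each round alone. Added after seeing the data were a filter on libraries with a rho of at least 0.25, rescaling each library to the same total, leaving out each library of the arms in turn, and the test of rho between proliferative and nonproliferative rafts. All columns were used. No sequence reads were analysed here.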

Results

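CFPAC-1 cells, an established human pancreatic ductal adenocarcinoma line, were profiled by RNA sequencing in 120 libraries. The first experiment compared cells picked on microrafts, which are small releasable culture elements of an array, with cells captured on the Fluidigm C1, a microfluidic instrument, and with bulk RNA. It held 4 bulk libraries, 10 libraries each of empty rafts, rafts with 1 cell and rafts with 2 cells, and 5 libraries each of empty, 1-cell and 2-cell C1 captures. The bulk and raft libraries were made in 2 rounds. The second experiment held 8 libraries of rafts scored as proliferative and 8 of rafts scored as nonproliferative in each of 4 arms: untreated, saline, 2 nM gemcitabine and 5 nM gemcitabine, a cytidine analog that blocks DNA synthesis. Another 7 libraries were made from water. Values were FPKM over 30504 rows, with column totals from 339644 to 817990. The table gives no counts, so the depth of each library is unknown and no counting interval can be given.

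Rafts with 1 cell averaged more genes than empty rafts and water, and fewer than C1 captures with 1 cell. Rafts with 1 cell had 6773 ± 1437 genes at an FPKM of 1 or more (SD, n = 10), against 590.3 ± 608 in empty rafts (n = 10), 536 ± 701 in water (n = 7) and 10027.5 ± 973 in bulk (n = 4). Empty rafts averaged 1164 genes in round 1 and 16.4 in round 2 (n = 5 each). C1 captures with 1 cell had 9223 ± 736 genes (n = 5) and empty C1 captures had 3545 ± 3066 (n = 5), with up to 7953 in a single empty capture, above the 4804 of the lowest raft with 1 cell. The raft-minus-C1 difference for 1 cell was -2449 genes, and -327.7 with detection at an FPKM of 5, where the ranges overlapped (4423 to 6766 in rafts and 5591 to 6621 in C1 captures). It was -1151 with the rafts of round 1 and -3748 with those of round 2, since the rounds themselves averaged 8072 ± 427 and 5475 ± 500 genes (n = 5 each). Rafts with 2 cells had 8833 ± 1078 genes, 2059.5 more than rafts with 1 cell (1571 more in round 1 and 2548 more in round 2). C1 captures with 2 cells had 10121 ± 1685 genes, 898 more than those with 1 cell, a difference that was 490.2 without C1 2-cell replicate 4 and 1404 without replicate 1. Bulk had 3254 more genes than rafts with 1 cell, 1471 more than those of round 1 and 5038 more than those of round 2.

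**Figure D1:**
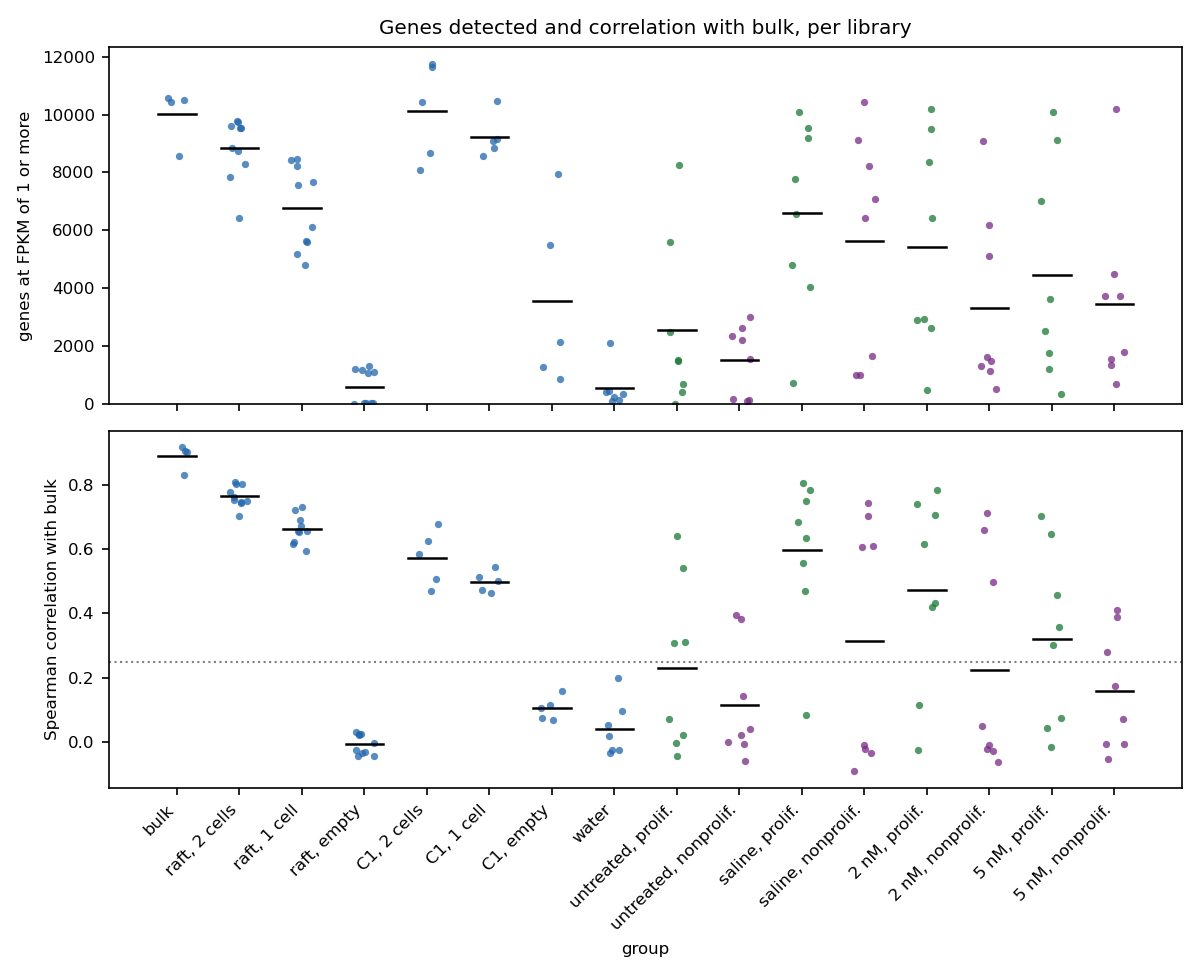
Genes detected at an FPKM of 1 or more (first panel, number of genes) and Spearman rho with the mean bulk profile (second panel), with 1 point per library by group, black lines for the group means and a dotted line at a rho of 0.25. Rafts with 1 cell average 6773 genes and a rho of 0.662, C1 captures with 1 cell 9223 genes and 0.499, and libraries of the treatment arms reach a rho of up to 0.807.

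Rafts with 1 cell ranked genes more like bulk than C1 captures did. Across 10767 genes with a mean bulk FPKM of 1 or more, Spearman rho with bulk was 0.662 ± 0.044 for rafts with 1 cell (SD, n = 10, range 0.595 to 0.732) and 0.499 ± 0.033 for C1 captures with 1 cell (n = 5, 0.463 to 0.544). The ranges did not overlap, and the difference of 0.164 was 0.181 in round 1 and 0.146 in round 2. These correlations run across genes, which are not independent replicates. Rafts with 2 cells reached 0.766 ± 0.033, C1 captures with 2 cells 0.573 ± 0.086, empty C1 captures 0.104 and single bulk libraries 0.891 ± 0.039. Of the genes detected, 25.2% in C1 captures with 1 cell and 8.38% in rafts with 1 cell had a mean bulk FPKM under 1. That share averaged 6.15% in the bulk libraries themselves. MTRNR2L genes, nuclear copies resembling the mitochondrial 16S RNA gene, took 1.96% of all FPKM in C1 captures with 1 cell, 0.290% in rafts with 1 cell and up to 49.3% in an empty C1 capture.

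Between single cells on rafts and on the C1, many genes of the cell division cycle were higher on rafts. UBE2S, a ubiquitin-conjugating enzyme of the anaphase-promoting complex, had a mean log2(FPKM + 1) of 8.33 ± 1.12 in rafts (SD, n = 10) and 0.13 ± 0.30 in C1 captures (n = 5). CDK1, the kinase that drives entry into mitosis, lay between 19.93 and 455.06 FPKM in all 10 rafts and between 251.57 and 582.59 FPKM in bulk, and it was listed at 0 in all 5 C1 captures. UBE2C, the partner of UBE2S, was higher by 6.88 on the log2 scale and detected in 9 of 10 rafts and 1 of 5 C1 captures. In the other direction, DHRS3, a retinal reductase, lay between 396.73 and 4637.08 FPKM in the C1 captures and between 11.81 and 59.46 FPKM in bulk, was detected in none of the 10 rafts, and differed by -10.47. Other genes with large differences were RANBP1 (7.38), PTHLH (7.01), AKR1C2 (6.90), SRXN1 (6.49), TUBA4A (6.39) and C1QBP (6.29). TFDP1, a partner of E2F factors, averaged 6.37 in rafts and was listed at 0 in all 5 C1 captures. Lower in rafts were SLPI (-8.27), TNFAIP2 (-7.95), FOS (-6.92), CRABP2 (-6.87), TOB1 (-6.44), KIF13B (-6.31) and PDZK1IP1 (-6.16). GABRP and TMPRSS4 averaged 8.60 and 8.46 in C1 captures and were listed at 0 in all 10 rafts. The median over all 10176 genes was -0.27, and -0.16 after quantile normalization.

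Of 46 G2/M genes, 44 were higher in rafts and 2 lower, with a median of 3.32, above all 10000 random lists of like expression. CKS2 differed by 6.27, and TACC3, which averaged 5.64 in rafts, was listed at 0 in all 5 C1 captures. Of 41 G1/S genes 37 were higher, with a median of 2.94, again above every random list. FEN1, which removes flaps in DNA replication, differed by 6.05, SLBP by 5.96, RRM2 by 5.04 and MLF1IP by 4.86. Genes of gemcitabine transport and metabolism were higher for 10 of 13 (median 2.72, percentile 99.96 of the random lists), with DCK, the kinase that activates gemcitabine, at 3.73, CDA, the deaminase that inactivates it, at 3.17, and NT5C at 3.70. NRF2 targets, of the response to oxidative stress, were higher for 15 of 17 (median 2.06, percentile 99.97), with GCLC at 4.46 and AKR1B10 at 4.33. Replication stress and DNA repair genes had a median of 0.93 (12 of 19 higher, percentile 97.85), with ATM at -3.29. Relative to bulk, the G2/M median was -1.16 in rafts with 1 cell (52 genes measured) and -3.56 in C1 captures with 1 cell (28 genes). The G1/S medians were -0.87 (42 genes) and -3.23 (35 genes). Each median thus covers the genes that passed the detection filter of its own comparison, and these sets differ.

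Interferon-stimulated genes were lower in rafts for 20 of 22, with a median of -2.81, below all 10000 random lists. XAF1 differed by -5.55, IFI6 by -5.28, IRF9 by -4.88 and MX2 by -3.79, while XAF1 also lay between 11.86 and 170.98 FPKM in all 5 empty C1 captures. Relative to bulk the interferon median was -1.37 in rafts (20 genes measured) and 1.09 in C1 captures (24 genes). NF-kB and inflammatory genes were lower in rafts for 12 of 15 (median -1.66, percentile 0.34), including LCN2 (-5.38), SAA2 (-3.78) and NFKBIZ (-3.44). Immediate early genes were lower for 10 of 11 (median -1.52, percentile 4.05), with EGR1 at -3.72 and JUN at -1.81. Epithelial and ductal markers were lower for 19 of 23 (median -1.34, or -0.87 after quantile normalization, percentile 0.04), with MUC1 at -4.49, ELF3 at -4.34, GRHL2 at -3.74 and SOX9 at -2.99. Mesenchymal markers were lower for 5 of 6 (percentile 0.48), with AXL at -4.17 and VIM, a mesenchymal filament protein, higher by 2.21. Ribosomal protein genes were lower for 55 of 75 (median -0.43), below all 10000 random lists of like expression. The unfolded protein response divided evenly, 8 of 16 higher and 8 lower (median -0.89, percentile 0.62), with CRELD2 at 5.48, SDF2L1 at 5.34 and ASNS at -3.81.

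The remaining lists lay between percentiles 17.53 and 87.21 of the random lists, where p53 targets had a median of 0.18 (percentile 81.01), with CDKN1A, an inhibitor of cyclin-dependent kinases, at 4.08. Apoptosis regulators had a median of 0.22 (72.51), with BAD at 4.51. Heat shock genes stood at 0.59 (70.66), glycolysis and hypoxia at 0.57 (87.21), oxidative phosphorylation at 0.50 (74.9), lysosome and autophagy at 0.36 (47.23), cholesterol synthesis at -0.36 (20.09) and drug efflux pumps at -1.88 (17.53). Quiescence and CDK inhibitors stood at -0.02 (49.69) and stem-like markers at -0.21 (25.95), and after quantile normalization these were -0.17 and 0.01, the p53 median 0.51 and the apoptosis median 0.39. With libraries rescaled to the same total the p53 and apoptosis medians were 0.0038 and 0.08, and the quiescence and stem-like medians -0.11 and -0.45. Among markers of other cell types, PTPRC of blood cells differed by -1.69, PECAM1 of endothelium by -0.89, KRT10 of keratinocytes by 5.04 and DMKN by -1.53. The C1 captures were a library set of their own, so method and set cannot be told apart, and no culture is named in the labels, so these differences carry no test.

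Some genes were detected in all rafts with 2 cells and in few rafts with 1 cell. SLPI, a secreted protease inhibitor, was detected in 10 of 10 rafts with 2 cells and 2 of 10 with 1 cell, and was higher by 4.69 on the log2 scale, with means of 5.73 ± 1.46 and 1.04 ± 2.33 (SD, n = 10 each). RAB25, an epithelial trafficking GTPase, was higher by 4.60, with the same detection in 10 and 2 rafts. HES4 was lower, at -2.61, detected in 4 of 10 rafts with 2 cells and 10 of 10 with 1 cell. Further genes higher with 2 cells were TSC22D3 (3.73), MED30 (3.68), FKBP11 (3.65), SNX10 (3.43), ATXN3 (3.34), CETN3 (3.34), CITED4 (3.25) and NRBF2 (3.14). Lower were FXYD6 (-2.22), SMCO4 (-1.97), CYP27A1 (-1.97) and MCM5 (-1.95), and RRAD was listed at 0 in all 10 rafts with 2 cells and detected in 5 of 10 with 1 cell. The median over 10660 genes was 0.40, 0.18 after quantile normalization, and -0.06 with the number of genes detected as a covariate.

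Of all 10660 genes 7998 were higher with 2 cells, and 17 of 18 NF-kB and inflammatory genes were, with a median of 1.03 (percentile 99.69 of the random lists). After quantile normalization 13 of 18 were higher, with a median of 0.64, and the medians were 0.35 for p53 targets, 0.15 for G1/S, 0.06 for oxidative phosphorylation and -0.20 for quiescence. The cytokines CXCL5 (2.15), CSF2 (1.97) and IL8 (1.79) and the inhibitor NFKBIA (2.10) were among them. Unfolded protein response genes were higher for 14 of 16 (median 0.99, percentile 99.89), with ASNS at 2.17 and MANF at 2.11. Immediate early genes were higher for all 11 measured (median 0.87, percentile 93.3, IER2 at 2.48), p53 targets for 18 of 19 (0.81, 93.75, GDF15 at 2.75), and epithelial markers for 24 of 25 (0.48, 82.03, CEACAM6 at 2.48). G2/M genes were higher for 40 of 51 (0.54, 80.19) and G1/S genes for 27 of 43 (0.32, 16.18). Oxidative phosphorylation genes divided 21 to 18 (0.02, 2.29), and quiescence genes 6 to 7 (-0.01, 1.82, or 0.07 with each library rescaled to the same total). Both rounds entered as a covariate, and these differences again carry no test.

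In the gemcitabine experiment many libraries had few genes. Across all arms, libraries of proliferative rafts had 4757 ± 3571 genes and those of nonproliferative rafts 3466 ± 3184 (SD, n = 32 each), a mean within-arm difference of 1291 genes (permutation p = 0.103, two-sided). Within arms the differences were 1045.5 genes in the untreated, 973 in the saline, 2129.9 in the 2 nM and 1015 in the 5 nM arm (exact permutation p = 0.398, 0.585, 0.227 and 0.565, two-sided, and 0.585 for each after Benjamini-Hochberg adjustment over the 4 arms). Single libraries moved them: leaving out 1 gave 229 to 1410 genes in the untreated, 311 to 1810 in the saline, 1448 to 2955 in the 2 nM and 212 to 1981 in the 5 nM arm. Spearman rho with bulk, compared after the data were seen, was 0.406 ± 0.293 in proliferative and 0.202 ± 0.282 in nonproliferative rafts, a difference of 0.204 (permutation p = 0.00427, two-sided). Within arms that difference was 0.118, 0.283, 0.249 and 0.164 in the same order (exact permutation p = 0.314, 0.0967, 0.139 and 0.180, adjusted 0.314, 0.240, 0.240 and 0.240). At least 1000 genes were detected in 26 of 32 libraries of either kind, the 52 libraries that entered the gene-level tests. That number was also reached by 5 of 10 empty rafts, 4 of 5 empty C1 captures and 1 of 7 water libraries. Among the 52 libraries 18 had a rho under 0.25. A rho of at least 0.25 was reached by 22 of 32 proliferative and 12 of 32 nonproliferative libraries.

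More genes were higher than lower in proliferative rafts when the 4 arms were averaged. The labels do not give the number of cells per raft in this experiment, so cell number and proliferation class cannot be told apart. APRT, which salvages adenine, rose by 5.31 ± 1.06 on the log2 scale (SE, limma adjusted p = 0.00205) and was detected in 23 of 26 proliferative and 10 of 26 nonproliferative rafts. HMGA1, an architectural chromatin protein, rose by 5.09 ± 1.01 (adjusted p = 0.00205; 25 and 16 rafts), and ENO1, the glycolytic enolase, by 5.25 ± 1.14 (adjusted p = 0.00247; 26 and 19 rafts). PCSK5, a proprotein convertase, changed the other way, by -3.07 ± 0.94 (adjusted p = 0.0239; 13 and 20 rafts), and reached 5767.21 FPKM in water and 7.22 FPKM in bulk. Of 11560 genes 1400 passed limma's two-sided test after Benjamini-Hochberg adjustment, 1313 higher and 87 lower, around a median over all genes of 0.58. After quantile normalization that median was 0.19 and the passing genes divided 533 to 127, and with the number of genes detected as a covariate 215 to 10. TAGLN2 (5.26), C19orf33 (5.20), SH3BGRL3 (5.04), AURKAIP1 (5.04), EIF4EBP1 (5.02), FAU (4.88) and TMSB10 (4.87) also rose. TMEM45A (-3.00), ASTN2 (-2.93), TBC1D8B (-2.93), C12orf50 (-2.45), MAB21L3 (-2.43), STX17 (-2.40), ADAMTSL3 (-2.39), IFNLR1 (-2.13) and SHISA9 (-2.12) fell, and TMEM45A reached 4378.65 FPKM in water and 6.09 FPKM in bulk. Saline nonproliferative replicate 3, which entered the test, had 10424 genes and a rho of -0.092. MORC4, PCSK5 and TMEM45A were among the highest genes both there and in water replicate 5.

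Ribosomal protein genes and oxidative phosphorylation genes had the highest medians in the 52 libraries, but medians of only 0.45 and -0.01 in the 34 with a rho of at least 0.25, below the cell cycle lists. Of 75 ribosomal protein genes 38 rose and none fell (55 adjusted over the list alone), with a median of 3.10, led by RPLP1 (4.86), RPS9 (4.49), RPS3 (4.40) and RPL36 (4.18). The list passed limma's camera test at an adjusted p = 1.12e-11, and not at the adjusted p = 0.795 with an estimated correlation. Of 39 oxidative phosphorylation genes 17 rose (31 adjusted over the list alone), with a median of 2.78, including UQCRC1 (4.71), ATP5G1 (4.17), COX6B1 (3.76) and NDUFA6 (3.73). Its camera adjusted p = 3.10e-07 became an adjusted p = 0.795 with an estimated correlation. Of 22 glycolysis and hypoxia genes 5 rose (7 adjusted over the list alone), namely ENO1, TPI1 (4.86), LDHA (4.82), ALDOA (4.22) and PGK1 (4.09). Of 10 heat shock genes 4 rose (4 adjusted over the list alone), DNAJA1 (4.08), HSPB1 (3.72), HSP90AB1 (3.63) and HSPD1 (3.17). Of 16 NRF2 targets 7 rose (9 adjusted over the list alone), among them SRXN1 (3.53) and PGD (2.90). The camera adjusted p was 0.0169 for glycolysis, 0.0206 for heat shock and 0.0132 for NRF2 targets, and for each the adjusted p = 0.795 with an estimated correlation. The fry test of whether a list moved one way on balance gave adjusted p = 0.00539 for ribosomal proteins, 0.00787 for oxidative phosphorylation, 0.00319 for glycolysis, 0.00539 for heat shock and 0.00721 for NRF2 targets.

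Cell cycle genes were higher in proliferative rafts as well. Of 43 G1/S genes 13 rose (26 adjusted over the list alone), including GINS2 (3.97), PCNA (3.29), SLBP (3.27) and FEN1 (3.11), and the list median was 1.46 against 0.58 for all genes. Of 52 G2/M genes 10 rose (22 adjusted over the list alone), including CKS2 (3.70), CDC20 (3.25), RANGAP1 (2.90) and AURKA (2.60), with a median of 1.35. After quantile normalization the medians were 0.80 for G1/S and 0.67 for G2/M, against 0.19 for all genes. Camera gave adjusted p = 5.35e-05 for G1/S and 2.80e-04 for G2/M, with the adjusted p = 0.795 and the adjusted p = 0.806 with an estimated correlation, and fry gave 0.00787 and 0.0182. CDK1 rose by 2.69. MKI67, a marker of cycling cells, differed by 0.58 ± 0.51 (adjusted p = 0.422) and TOP2A by 1.67 ± 0.75 (adjusted p = 0.110), so neither passed. CDKN1A rose by 3.38 ± 0.87 (adjusted p = 0.00811). Of 15 genes of gemcitabine transport and metabolism 2 rose (6 adjusted over the list alone), DCTD (2.88) and RRM1 (1.93), with a camera adjusted p = 0.0248 and the adjusted p = 0.795 with an estimated correlation. DCK (0.83, adjusted p = 0.329), CDA (2.21, 0.0913), RRM2 (1.46, 0.170), TYMS (1.68, 0.0661) and SLC29A1 (1.78, 0.0608) did not pass.

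In the other lists up to 5 genes rose in proliferative rafts, and none fell. Over all 11560 genes 1313 rose, and several of these lists held a like or lower share of rising genes, so their counts do not set them apart. Of 24 apoptosis regulators 5 rose (9 adjusted over the list alone), BAD (3.78), BCL2L1 (2.25), BIRC2 (2.12) and MCL1 (1.95) among them. Of 24 interferon-stimulated genes 4 rose, among them IFI27 (3.92), ISG15 (3.80) and ISG20 (3.49). Of 17 unfolded protein response genes 5 rose, TRIB3 (3.24), SDF2L1 (3.16), DDIT3 (2.99), CRELD2 (2.05) and CHAC1 (1.38), and of 20 cholesterol synthesis genes 4 rose, ACAT2 (3.09), MVD (2.24), DHCR7 (2.06) and FDPS. Of 19 p53 targets 4 rose, CDKN1A, CCNG1 (2.07), PLK3 (1.81) and AEN (1.74). Of 25 epithelial and ductal markers 3 rose, KRT7 (3.91), KRT8 (3.68) and CLDN7 (2.15). Of 20 NF-kB genes 2 rose, CSF2 (2.39) and TNFAIP3 (1.61). Of 8 mesenchymal markers 2 rose, VIM (3.37) and SNAI2 (1.97), and the list did not pass camera (adjusted p = 0.812), with a median of 0.25 against 0.58 for all genes. Of 12 quiescence genes 2 rose, CDKN1A and CDKN2A (3.07), of 21 lysosome and autophagy genes 2 rose, SQSTM1 (3.78) and ATP6V0D1 (3.37), of 10 immediate early genes JUNB (1.80) rose, and of 10 stem-like markers BMI1 (2.70) rose. The quiescence median of 0.70 and the stem-like median of 0.31 became -0.03 and -0.02 after quantile normalization. None of 24 replication stress genes and none of 4 drug efflux pumps passed limma's test. Among markers of other cell types, DMKN (2.67) of keratinocytes rose, and the fibroblast marker and the endothelial marker measured did not pass.

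The count of passing genes depended on which libraries were kept. It was 780 without untreated proliferative replicate 3, 783 without replicate 4 of that group, 906 without saline nonproliferative replicate 1 and 881 without replicate 4 of that group. Among the 34 libraries with a rho of at least 0.25, a filter added after the data were seen, 94 of 10083 genes passed (72 higher and 22 lower; 22 and 12 libraries). HMGA1 rose there by 4.36 ± 0.61 and APRT by 3.97 ± 0.55, with detection of HMGA1 in 22 of 22 proliferative and 10 of 12 nonproliferative rafts. Of 22 glycolysis genes 2 rose, ENO1 (2.03) and TPI1 (2.77), with ALDOA and PGAM1 added when adjusted over the list alone. Of 75 ribosomal protein genes 3 rose, RPS9 (2.02) and RPLP1 (1.68) among them, and 8 adjusted over the list alone, with a median of 0.45, and of 39 oxidative phosphorylation genes UQCRC1 (3.24) and CYC1 (3.21) rose and COX6A1 (-2.49) fell, with a median of -0.01. No G1/S gene and no G2/M gene passed limma's test over all genes there, and their medians were 1.11 and 0.83 against 0.32 for all genes. SHISA9, lower in the 52 libraries, stood at 0.05 in the 34.

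**Figure D2:**
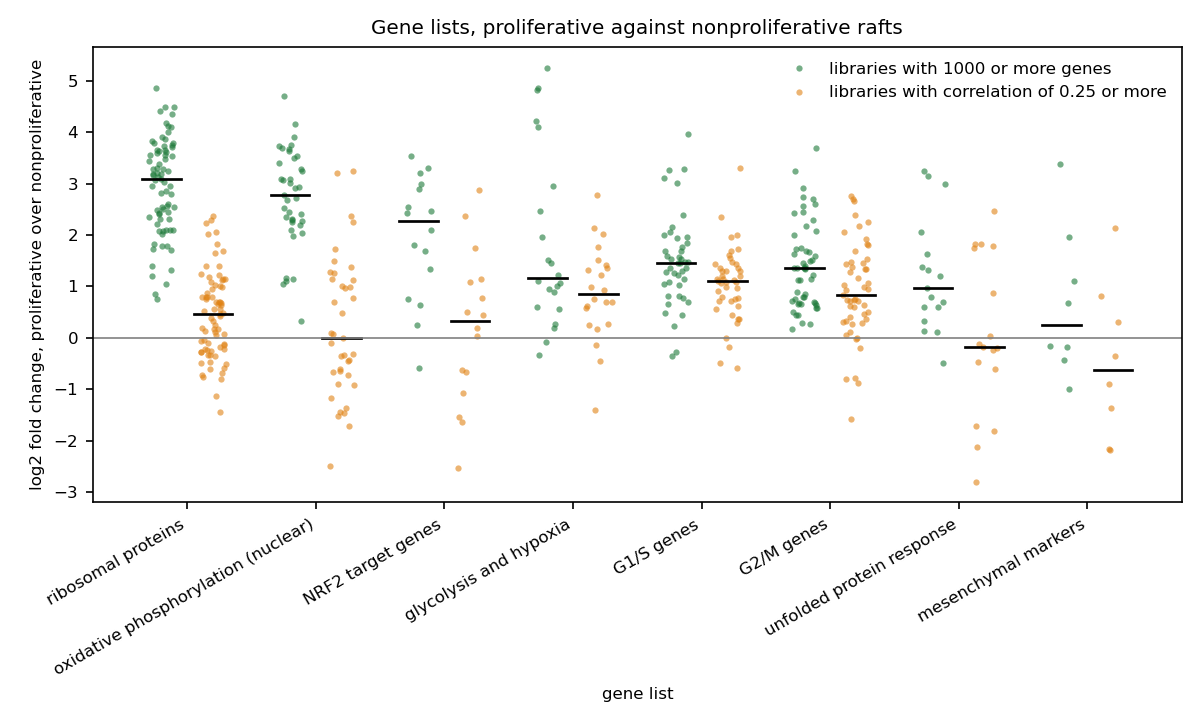
log2 fold change between proliferative and nonproliferative rafts, averaged over 4 arms, for the members of 8 gene lists in the 52 libraries with at least 1000 genes and in the 34 libraries with a rho with bulk of at least 0.25, with 1 point per gene and black lines for medians. The ribosomal protein median is 3.10 in the first set and 0.45 in the second, and the G1/S median is 1.46 and 1.11.

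Within single arms few genes separated proliferative from nonproliferative rafts. In the 2 nM arm WDR4, a cofactor of tRNA methylation, rose by 4.92 ± 1.05 (SE, limma adjusted p = 0.0386; detected in 6 of 7 and 1 of 7 rafts). MCCC1, of leucine breakdown, rose from a level listed at 0 in all 7 nonproliferative rafts to detection in 7 of 7 proliferative rafts (adjusted p = 0.0386). Neither passed limma's test after quantile normalization (1205 genes at an unadjusted p under 0.05), with a pseudocount of 0.1 (1396), with libraries rescaled to the same total (1274) or among libraries with at least 3000 genes (439). No gene passed limma's test in the untreated arm (808 at an unadjusted p under 0.05), the saline arm (1272) or the 5 nM arm (1030). The smallest p-values belonged to STRN4 (detected in 4 of 5 and 0 of 5 rafts, adjusted p = 0.334) in the untreated arm, SMYD5 and MMP1 in the saline arm (adjusted p = 0.145 and 0.249), and PPDPF (4.91, 0.0749) and RAB5C (6.92, 0.115) in the 5 nM arm. CDKN1A stood at 6.59 in the untreated arm (adjusted p = 0.334) and CCNB1 at 5.99 in the saline arm (0.364). In the saline arm 6 of 52 G2/M genes, among them CKS2 (5.45), UBE2C (5.13) and AURKA (4.53), and 3 of 43 G1/S genes, CDC6 (4.68), MCM2 (4.33) and CHAF1B (4.01), rose when adjusted over the list alone and none over all genes. The camera adjusted p was 1.47e-09 for G2/M and 8.03e-06 for G1/S, and the adjusted p = 0.736 with an estimated correlation for both. No gene passed limma's test of whether the proliferation difference itself differed between gemcitabine and control arms (225 at an unadjusted p under 0.05), with TLR10 (2.71) among the smallest p-values. Leaving out 1 library moved the 2 nM count between 0 and 7, with 13 of 14 libraries moving it by over 1.5 times, and the untreated count to 20 without untreated proliferative replicate 5. Among libraries with a rho of at least 0.25 the counts were 70 untreated (4 proliferative and 2 nonproliferative libraries), 1 saline (MMP1, lower; 7 and 4), 2 at 2 nM (GJB1 and SLC34A2, both lower; 6 and 3), 53 at 5 nM (5 and 3) and 1 between gemcitabine and control arms (TRMT112, lower).

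Saline rafts had higher levels than untreated rafts, mean over both proliferation classes. Their libraries also had more genes, with means of 6591 (proliferative) and 5618 (nonproliferative) against 2557 and 1511, and mean rho of 0.597 and 0.313 against 0.231 and 0.113. PHLDA2, an imprinted growth regulator, rose by 5.65 ± 1.23 (SE, limma adjusted p = 0.0357) and was detected in 11 of 14 saline and 1 of 10 untreated rafts. NOB1, an endonuclease of ribosome assembly, rose by 5.15 (adjusted p = 0.0333; 13 of 14 and 1 of 10 rafts). ZEB1, a mesenchymal transcription factor, rose by 2.62 ± 0.65 (adjusted p = 0.0391; 10 of 14 and 0 of 10 rafts), the only one of 8 mesenchymal markers to pass. AIMP2 was detected in 11 of 14 saline rafts and listed at 0 in all 10 untreated rafts that entered. AAMDC (5.49), IMP4 (5.22), MT1X (5.02), POLR2H (4.79), POP7 (4.78) and PITPNB (4.54) also rose. In all 44 genes rose and none fell (3344 genes at an unadjusted p under 0.05), around a median over all genes of 1.09, which was 0.34 after quantile normalization, where no gene rose and PARD6B fell. With the number of genes detected as a covariate no gene passed limma's test (494 at an unadjusted p under 0.05). Among libraries with a rho of at least 0.25 (11 saline and 6 untreated) 560 rose and 4 fell. The filter did not even out genes detected, with 4029 to 10099 in those saline and 1495 to 8271 in those untreated libraries. With all libraries 3021 genes passed, and 1287 with only the groups compared. Of 43 G1/S genes none passed over all genes and 12 rose adjusted over the list alone, with a camera adjusted p = 0.0796 and the adjusted p = 0.999 with an estimated correlation. DCK (2.37, adjusted p = 0.0859) and SLC29A1 (3.12, 0.0624) did not pass. Each arm was a library pool of its own, so arm and pool cannot be told apart, here and in the gemcitabine comparisons. Leaving out 1 library moved the count between 0 and 1483 (highest without untreated proliferative replicate 3), with 23 of 24 libraries moving it by over 1.5 times. No gene passed in 13 of those 24 cases.

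With 5 nM gemcitabine a stress gene rose and a broad set of genes fell relative to saline. Libraries at 5 nM had fewer genes, with means of 4452 (proliferative) and 3436 (nonproliferative) against 6591 and 5618, a difference of -2419.2 among the libraries tested, and mean rho of 0.321 and 0.157 against 0.597 and 0.313. ATF3, a transcription factor induced by stress, rose by 3.58 ± 0.81 (SE, limma adjusted p = 0.0111), with detection in 8 of 14 rafts at 5 nM and 2 of 14 with saline. S100P, a calcium-binding protein, rose by 3.81 ± 1.12 (adjusted p = 0.0333; 9 and 5 of 14 rafts), and ARRDC4 by 2.48 ± 0.76 (adjusted p = 0.0412; 7 and 4). BAD, a promoter of apoptosis, changed by -4.91 ± 1.11 (adjusted p = 0.0111), with detection in 3 of 14 rafts at 5 nM and 11 of 14 with saline. DCK, the kinase that activates gemcitabine, changed by -2.56 ± 0.81 (adjusted p = 0.0467). The genes that changed most were C19orf48 (-5.46 ± 1.17, adjusted p = 0.0111; 2 and 12 of 14 rafts), NDUFAB1 (-5.31), STUB1 (-5.25), DUS1L (-5.06), NHP2 (-5.06), BLVRA (-4.99), TUBA1B (-4.98), PPA2 (-4.96) and CDC123 (-4.91), all lower. Of 11560 genes 9 rose and 527 fell by limma's two-sided test after Benjamini-Hochberg adjustment, around a median over all genes of -0.76. After quantile normalization that median was -0.23, and 8 genes rose and 99 fell.

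Of 16 NRF2 targets 3 fell at 5 nM (4 adjusted over the list alone), TXNRD1 (-3.85), SRXN1 (-3.75) and ME1 (-2.02), with a median of -1.77 and a camera adjusted p = 0.0835. Of 24 apoptosis regulators 3 fell (4 adjusted over the list alone), BAD, BIK (-3.63) and FADD (-2.88). Of 15 genes of gemcitabine transport and metabolism 2 fell (3 adjusted over the list alone), DCK and NT5C (-3.19), with a median of -1.65. SLC29A1 (-2.39, adjusted p = 0.0866), RRM1 (-1.99), RRM2 (-2.19), CDA (-1.17) and TYMS (-0.83) did not pass. Of 43 G1/S genes 1 fell, CHAF1B (-2.81), with a median of -1.59 and a camera adjusted p = 0.0116, against the adjusted p = 0.903 with an estimated correlation. Of 52 G2/M genes 2 fell, TUBB4B (-4.35) and AURKA (-3.05), with a median of -1.29 and a camera adjusted p = 0.130. TOP2A (-2.67, adjusted p = 0.0866), PCNA (-2.48, 0.163) and MKI67 (-0.50) did not pass. Of 19 p53 targets TRIAP1 (-3.64) fell, and adjusted over the list alone GDF15 (2.37) rose and DDB2 (-2.25) and CCNG1 (-2.62) fell with TRIAP1, while CDKN1A stood at -0.32. After quantile normalization the medians were 0.03 for p53 targets (-0.55 without it), -0.59 for gemcitabine transport and metabolism, -0.82 for G1/S and -0.71 for G2/M.

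NF-kB and inflammatory genes stood above the other genes at 5 nM, with a median of 0.33 against -0.76, though none of 20 passed limma's test on its own or adjusted over the list alone. Their camera adjusted p = 1.34e-04 became an adjusted p = 0.903 with an estimated correlation. Of 10 immediate early genes only ATF3 rose (median 0.08, camera adjusted p = 0.00384, and the adjusted p = 0.903 with an estimated correlation). Of 25 epithelial markers S100P rose and of 24 interferon-stimulated genes BST2 (-4.28) fell. Camera placed both lists above the other genes (adjusted p = 0.0352) while their medians were -0.10 and -0.02, or 0.27 for both after quantile normalization, and both had the adjusted p = 0.903 with an estimated correlation. Of 8 mesenchymal markers ZEB1 (-2.45, adjusted p = 0.0149) fell. Of 39 oxidative phosphorylation genes UQCRC2 (-3.21) fell, and that list, with a median of -1.11, did not pass camera (adjusted p = 0.773). No member passed among heat shock genes (median -1.82), glycolysis (-1.14), lysosome and autophagy (-1.11), ribosomal proteins (-0.72), replication stress (-0.62), cholesterol synthesis (-0.38) and drug efflux pumps (-0.35). After quantile normalization the medians moved by over 1.5 times to -0.63 for glycolysis, -0.48 for lysosome and autophagy, -0.13 for replication stress and for cholesterol synthesis, -0.04 for drug efflux pumps, 0.29 for immediate early genes and 0.82 for NF-kB genes. None passed either among unfolded protein response genes (-0.42), quiescence genes (-0.21) and stem-like markers (-0.20), whose medians were 0.00, 0.61 and 0.54 after quantile normalization, nor among the markers of other cell types.

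**Figure D3:**
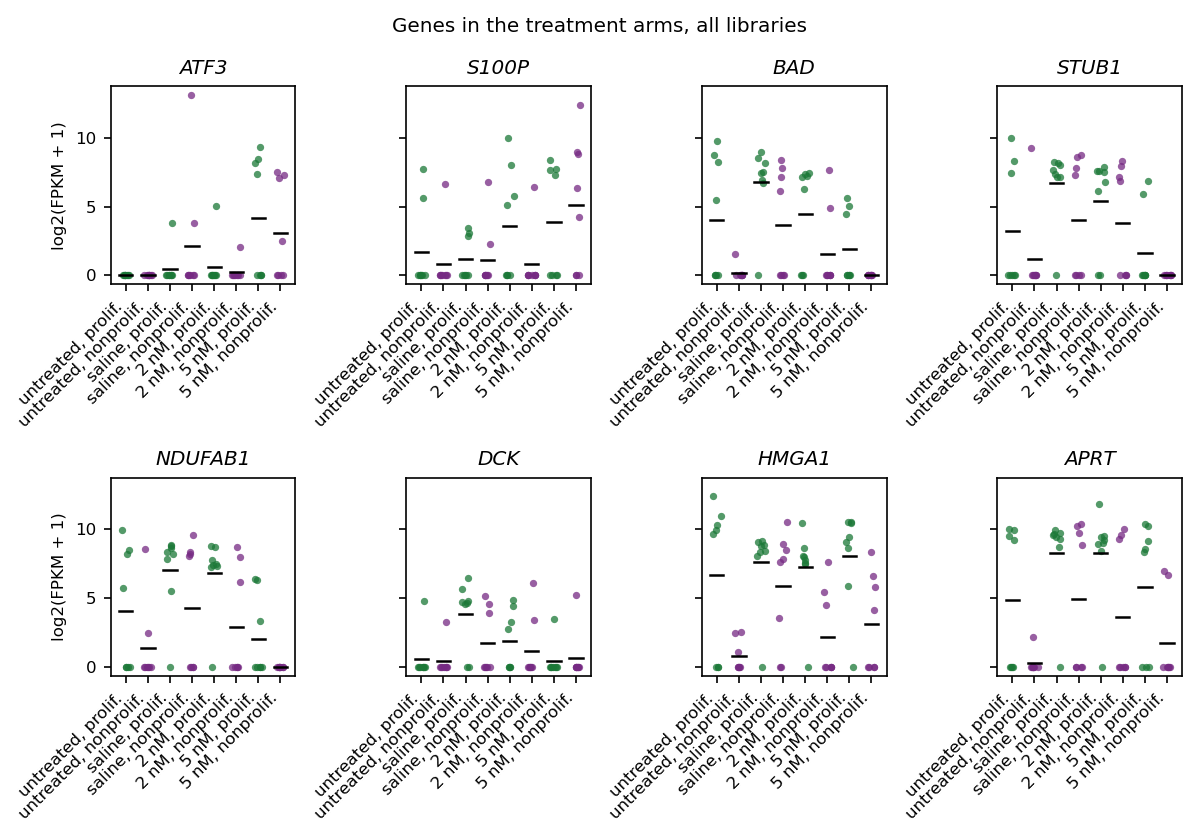
log2(FPKM + 1) of ATF3, S100P, BAD, STUB1, NDUFAB1, DCK, HMGA1 and APRT in the 8 groups of the gemcitabine experiment, with 1 point per library (n = 8 per group, all libraries, green for proliferative and purple for nonproliferative) and black lines for means. ATF3 is detected in 8 of the 5 nM rafts that entered the test and in 2 of the saline rafts, and BAD in 3 and 11.

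The 5 nM count moved with the libraries. It was 108 without saline nonproliferative replicate 6 and 1234 without 5 nM proliferative replicate 2, with 21 of 28 libraries moving it by over 1.5 times, and with the number of genes detected as a covariate 9 genes passed, 5 higher and 4 lower. Among the libraries with a rho of at least 0.25 (8 at 5 nM and 11 with saline) 41 genes rose and 566 fell. ATF3 stood at 5.50 there (detected in 6 of 8 and 1 of 11 rafts) and S100P at 5.91. BAD stood at -6.06, BST2 at -5.12, HSPA8 at -3.15, TPI1 at -2.16 and ENO1 at -1.90. Genes detected still differed, with 1759 to 10075 in the 5 nM and 4029 to 10099 in the saline libraries kept. In those libraries 3 of the NF-kB genes rose adjusted over the list alone, IL8 (4.48), CXCL2 (3.63) and TNFAIP3 (2.58), with a camera adjusted p = 5.35e-08 and the adjusted p = 0.359 with an estimated correlation.

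With 2 nM gemcitabine no gene passed limma's test against saline (768 at an unadjusted p under 0.05). The smallest p-values belonged to GNB1L, detected in 7 of 14 saline rafts and listed at 0 in all 14 rafts at 2 nM, HOPX (-2.99), PYGO2 (-2.49), CNEP1R1 and TRDMT1. Between 5 nM and 2 nM no gene passed limma's test either (979 at an unadjusted p under 0.05), with ATF3 at 3.62 ± 0.81 (SE, adjusted p = 0.193), WDR4 detected in none of 14 rafts at 5 nM, SPIB at 2.27 and NDUFAB1 at -4.39. Median changes over all genes were -0.52 and -0.28. Among libraries with a rho of at least 0.25, 52 genes passed between 5 nM and 2 nM, 3 higher and 49 lower, with ATF3 at 5.01, LCA5L at 2.87 and NDUFAB1 at -6.16, and none passed between 2 nM and saline (463 at an unadjusted p under 0.05).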

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

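The tests of other splits of the libraries were planned, and the tests of technical explanations in the next 3 paragraphs were chosen after the results were seen.

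Genes higher in proliferative rafts had a median log2 fold change of 2.58 over the 1313 genes. A candidate explanation is libraries with little or no cell RNA. Among libraries with a rho of at least 0.25 the median was 1.69, below the 5th lowest of 99 random draws of as many libraries (1.63 to 3.78). There 1293 of the 1313 genes kept their direction, which adds no support, because they were chosen in a set that included those libraries. Low-rho libraries, some of them with abundant cell transcripts such as RPS14, may account for part of the size. A difference in genes detected cannot be told apart, because with that number as a covariate the median was 1.88 and the covariate may itself follow the cells. The number of cells per raft, which the labels do not give, cannot be told apart either. Proliferation of the cells stays open as a hypothesis. In the libraries with a rho of at least 0.25 the G2/M median lay at percentile 99.38 of random lists, with 44 of 51 genes above 0. The random lists were drawn gene by gene, so the percentile does not allow for G2/M genes that move together within libraries. No G2/M gene passed limma's test over all genes there, and no camera call held with an estimated correlation. Only 1 of 100 splits of the libraries gave as many genes, the real one. It gave 1400 genes, against 1297 in the highest other split, 435 in the next and a median of 0. The real split thus ranked first with another close to it, which does not exclude chance.

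Genes lower at 5 nM than with saline had a median of -3.24 over 527 genes. Libraries without cell RNA in the 5 nM arm are a candidate explanation. Leaving out those with a rho under 0.25 did not shrink the change, with a median of -3.81 among the rest. That was beyond the median of 99 random draws (-3.26) and within their range (-4.32 to -2.08). The libraries kept still differed, with rho from 0.280 to 0.703 at 5 nM and from 0.470 to 0.807 with saline. Little cell RNA in the 5 nM arm was thus not excluded. There 527 of 527 genes kept their direction, which adds no support, because they were chosen in a set that included those libraries. A difference in genes detected cannot be told apart, with a median of -2.16 when it entered as a covariate. A difference between library pools cannot be told apart either, because each arm was 1 pool, and saline against untreated, also different pools, gave 44 genes. In 2 of 100 splits, the real one included, as many genes passed (536, and 545 in the highest other, with a median of 0 over the others). Another split thus gave more genes than the real one, so chance was not excluded. Gemcitabine itself stays open and untested apart from the pool.

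C1 captures with 1 cell correlated less with bulk and held less of the G2/M genes than rafts with 1 cell. Bulk made in the same rounds as the rafts was argued against, since the lowest rho of a raft with the bulk of the other round was 0.589 and the highest C1 rho with either round 0.540, and since with any bulk library alone, whichever its round, these were 0.548 and 0.529. The estimate of relative depth went against lower depth of the C1 captures, with a median of 5.76, against 1.64 in rafts. That is weak evidence, because the estimate was off by up to a factor of 2.0 on simulated data. Those data held no library deeper than its reference, and over the reference libraries the estimates varied by a median factor of 2.01. A difference between the raft rounds was argued against by a G2/M median difference of at least 2.72 within each round. The method and the library set cannot be told apart, so the handling of the cells, their state and the set may each contribute.

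Splits of the other comparisons were read in the same way, each over 100 splits including the real one. For saline against untreated 1 split gave as many genes, with 44 in the real one and 15 in the highest other. A rank of 1 in 100 does not exclude chance over the comparisons made, and leaving out 1 library left no passing gene in 13 of 24 cases. For proliferation in the 2 nM arm 4 splits gave as many, with 2 genes in the real one and 2349 in the highest other, which points to structure among those libraries, also untested. For comparisons in which no gene passed, all 100 splits necessarily gave as many, so they say nothing about chance. The highest other split gave 1 gene for proliferation in the untreated arm, 351 in the saline arm, 329 in the 5 nM arm, 0 for the difference between gemcitabine and control arms, 607 for 2 nM against saline and 210 for 5 nM against 2 nM. The counts of 351, 329, 607 and 210 point to structure of the libraries in those splits, which was not tested, and the next highest were 232, 24, 1 and 2, with a median of 0 in each.

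Single libraries stood far from the rest of their group in 5 of 32 combinations of group and measure tested. Chance gives about 1 in 20 only where values spread normally and measures are independent. Neither was shown here, and bulk replicate 1 entered by both measures, so no excess over chance is claimed. Water replicate 5 had 2097 genes detected, against 81 to 428 in the others. Bulk replicate 1 had 8570 genes, against 10444 to 10581. Its rho was 0.833, against 0.905 to 0.919. Saline proliferative replicate 5 had a rho of 0.0826, against 0.470 to 0.807. Nonproliferative replicate 7 at 5 nM had 10198 genes, against 688 to 4478.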

How the results depend on the processing

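The filter on rho and the rescaling to the same total were chosen after seeing the data, as were the quantities followed for 1 cell (G2/M median) and for 2 cells against 1 (median over all genes). No paired analysis was possible because equal replicate numbers in different groups name unrelated rafts. The filter at 3000 genes was not run for proliferation averaged over arms, in the untreated arm and between gemcitabine and control arms, nor for saline against untreated, since no untreated nonproliferative library reached it; thinning was not run without counts. Depth is unknown, so a gene listed at 0 was not shown to be absent. Named genes kept direction and threshold in 455 of 646 gene and setting pairs for proliferation, 196 of 269 for 5 nM against saline, 69 of 99 for saline against untreated and 6 of 18 in the 2 nM arm. These shares varied by setting. For proliferation they ran from 80 of 81 genes with rescaling to 26 of 81 with genes detected as a covariate and 15 of 80 with the rho filter. With the covariate 4 of 27 genes held for 5 nM and 0 of 11 for saline, where 0 of 11 held after quantile normalization too. The cause was not tested for the changes that follow, except where fewer libraries or genes entered.

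With detection at 5, rafts minus C1 was -327.7 genes, rafts minus empty rafts 5014.9, C1 minus empty 3399.4 and bulk minus rafts 976. Round 1 alone gave -1150.8 for rafts minus C1 and 1470.7 for bulk minus rafts, round 2 alone -3748.0 and 5037.9. The G2/M median was 4.49 with a pseudocount of 0.1 and 4.73 in round 2, and for 2 cells the median was 0.88 with that pseudocount and -0.057 with genes detected as a covariate. Quantile normalization gave 660 genes for proliferation over arms, 5 in the untreated (all lower, TERF2 and IL4I1 among them), 0 in the 2 nM and 3 in the 5 nM arm (RAB5C, PPDPF and SNHG5), 1 for saline against untreated (PARD6B, lower) and 107 for 5 nM against saline. A pseudocount of 0.1 gave 0 in the 2 nM arm, 887 and 877 for the latter 2 comparisons. No gene filter gave 855 for proliferation, 1 in the 2 nM (MCCC1) and 1 in the 5 nM arm (PPDPF), 7 for saline and 307 for 5 nM. A stricter gene filter, relative to the number of libraries, gave 4 in the 2 nM arm (KRT86 and FKBP1A-SDCBP2 added) and 498 for saline. All libraries gave 641, 3021 and 340 for proliferation, saline and 5 nM. Libraries with 3000 genes gave 0 in the 2 nM arm, 31 in the 5 nM arm and 385 for 5 nM against 2 nM. The covariate gave 225 for proliferation, 2 in the saline arm (SMYD5 and N6AMT2), 1 in the 2 nM arm (MCCC1) and 3 in the 5 nM arm (RAB5C, PPDPF and SNHG5), 0 for saline against untreated and 9 for 5 nM against saline. Only the groups compared gave 0 in the 2 nM arm, 1287 and 867 for saline and 5 nM, and rescaling gave 0 in the 2 nM arm. The rho filter gave 94 for proliferation (SHISA9 at 0.047), 70, 1, 2 (lower) and 53 in the arms, 1 between gemcitabine and control arms (TRMT112, lower), 564 for saline and 52 for 5 nM against 2 nM.

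The name of bulk replicate 3 gives another round than its index pair, so after seeing the data each bulk library alone served as reference, and replicates 1, 2 and 3 together, with a rho difference of 0.158 to 0.182.

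Leaving out 1 C1 library each, rafts minus C1 ran from -2615 to -2137 genes, C1 minus empty from 5007 to 6779, C1 2 minus 1 cells from 490.2 to 1404 and the rho difference from 0.155 to 0.175, and leaving out 1 bulk library bulk minus rafts ran from 3069.8 to 3740.1. No raft library was left out there. Within arms, where each library was left out in turn after the data were seen, the difference in genes between proliferation classes ran from 229 to 1410 (untreated), 311 to 1810 (saline), 1448 to 2955 (2 nM) and 212 to 1981 (5 nM). That in rho ran from 0.0588 to 0.158, 0.225 to 0.357 (unadjusted exact permutation p = 0.0488 without saline proliferative replicate 5 and 0.0466 without nonproliferative replicate 6), 0.205 to 0.321 and 0.110 to 0.213. For 1 cell, without 1 C1 library, the medians ran from 3.07 to 3.55 (G2/M), 2.69 to 3.07 (G1/S), -2.77 to -2.42 (interferon) and -1.53 to -0.96 (epithelial). Leaving out 1 library of the groups compared, counts ran from 780 to 2067 for proliferation, 0 to 20 in the untreated and 0 to 7 in the 2 nM arm, 0 to 1483 for saline and 108 to 1234 for 5 nM. Between gemcitabine and control arms only the 10 untreated libraries were left out in turn, each with 0 genes by limma (200 to 252 at an unadjusted p under 0.05).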

Other observations

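Among the 34 libraries with a rho of at least 0.25, selected after seeing the data, proliferative rafts differed in further genes. PRSS3, a trypsin, rose by 4.62 (limma adjusted p = 0.00599), and KRT86 (4.07), COPE (3.82), NCL (3.66), BRMS1 (3.64), EIF4EBP1 (3.63), SMOX (3.60) and CHCHD4 (3.58) rose as well. TCN1, a carrier of vitamin B12, changed by -4.94 ± 1.10 (SE, adjusted p = 0.0116), detected in 15 of 22 proliferative and 12 of 12 nonproliferative rafts. TMEM59 (-4.37), SSR4 (-3.84), CNIH4 (-3.76), PIGF (-3.39) and SGCB (-3.36) fell, as did MTRNR2L10 (-3.90), MTRNR2L1 (-3.86), MTRNR2L8 (-3.41) and MTRNR2L6 (-3.34). SQSTM1 (2.65) and KRT8 (2.03) rose. CDKN1A (2.64, adjusted p = 0.116) and MKI67 (0.10, adjusted p = 0.969) did not pass.

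Between C1 captures with 2 cells and with 1 cell, 20 of the 23 G2/M genes measured out of 54 were higher with 2, with a median of 1.13, and 15 of 23 G1/S genes, with a median of 0.39, against 0.14 over 10117 genes. CKS2 was higher by 3.58, HMGB2 by 3.26, BIRC5 by 3.26 and CCNB2 by 2.37. SPP1 (4.76), RHBDD2 (4.58) and S100P (3.43) were higher and TADA2A (-3.64), TRIB3 (-2.84) and KRT7 (-2.40) lower. Relative to bulk, NRF2 targets had a median of 1.90 in rafts with 1 cell (17 genes measured) and -1.14 in C1 captures with 1 cell (14 genes). Immediate early genes stood at -0.44 (8 genes) and 1.29 (11 genes). These values carry no test, and the lists between C1 captures with 2 cells and 1 cell were not set against random lists.

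ATF3 reached 8869 FPKM in a single saline nonproliferative library. No 2 libraries of a group had identical columns.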
